A study of Mus musculus with 24 samples.

How the data were processed

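RNA from NIH/3T3 mouse fibroblasts treated for 24 h at 37 °C with halofuginone (100 nM in the sample labels) or PBS was sequenced as total RNA and as 3 pools of polysome gradient fractions. Per the labels' protocols, cells grew in medium with 10% bovine calf serum, RNA was taken with TRIzol and treated with DNase, libraries came from the TruSeq Stranded mRNA kit, and sequencing ran on a HiSeq2500 instrument. The kit selects polyadenylated RNA, so RNAs without a poly(A) tail are measured only in part. No spike-in is mentioned, and each library was scaled to its own total, so the values compare shares of each pool and not amounts of RNA per cell.

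The authors deposited a single table of counts per gene symbol for the 24 libraries, whose values are whole numbers with a different sum in each library. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.0p3 with featureCounts, and the genome build GRCm38.p5 were used. Their roles, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Genes that overlap, or that share sequence with paralogs or pseudogenes, are therefore less certain. The table held no column of another sample (0 such columns) and 49568 gene symbols. Of these, 47240 were found in the GENCODE M21 annotation of GRCm38, which supplied gene coordinates, and 21144 had a complete coding sequence there.

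Column headers were matched to the 8 groups by treatment and by gradient fraction numbers, but not to single samples within a group. The headers of 8 columns (set A) carry a date-like tag and those of halofuginone give 50 nM, and the other 16 (set B) carry tags 2, 3 or 4. The labels give 1 dose for all samples, and the dose in set A is not settled here. A column tag was used as a replicate block only as an alternative. Whether tags pair the libraries was judged by the correlation across genes of their deviations from group means, as no label ties a tag to a shared culture. Between treatments, same-tag libraries correlated at 0.925, 0.844 and 0.807 in the ribosome-free pool, 0.807, 0.702 and 0.410 in light and 0.774, 0.729 and 0.361 in heavy polysomes. Between the ribosome-free and heavy pools they correlated at 0.255, 0.442 and 0.460 in vehicle and 0.396, 0.213 and 0.214 with halofuginone. The highest correlation between different tags was 0.325 in the ribosome-free pool, 0.005 in light and -0.030 in heavy polysomes. Between the ribosome-free and heavy pools it was -0.097 in vehicle and 0.024 with halofuginone. These values allow a paired fit of the pools, but all counts, errors and p-values of the pools come from unpaired fits unless the block is named. These correlations are across genes, which are not independent replicates.

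The groups, the 7 comparisons with their tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Each fraction was fitted alone from its 6 libraries, and the 2 differences of differences from 12, with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts. TMM scaling, edgeR's default expression filter and a Benjamini-Hochberg threshold of 0.05 were used. Values in CPM are TMM-scaled within a fraction, given as mean ± SD over libraries, and log2 fold changes are given with their standard errors. Of 25 fixed gene lists, 21 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated. The other 4, markers of epithelial cells, leukocytes, endothelial cells and adipocytes, are given as levels. Amino acid sets held the 10% of genes with the largest share of each of 20 amino acids in the longest annotated protein, tested in the same way. They were also tested with the fold changes corrected for GC content and length. That test used the corrected fold changes alone and not the counts, so it differs from camera on counts by more than the correction.

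Named genes followed a rule. In every comparison 12 fixed genes were named where tested (Eprs, Atf4, Ddit3, Asns, Trib3, Col1a1, Col1a2, Col3a1, Fn1, Ltbp2, Sulf1, Acta2). The 6 largest rises and 6 largest falls, or 3 of each outside total RNA, heavy polysomes and their difference, were named among called genes with a mean of at least 5 CPM in a group and replicates that did not overlap, leaving out predicted genes and pseudogenes. From each list that passed camera or had 5 called members came the 2 called members with the largest change, or else the member with the smallest p. The rule was applied again to set B of total RNA. Other genes are said to be named after their values were seen. In that set Atp13a4, Tenm2, Bdkrb1, Galnt15, Steap4 and Apol6 met the rule but had counts of 0 in a whole group, and no fold is given for them.

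The alternatives were DESeq2 1.42.0 with its own size factors, edgeR with median-of-ratios factors, no filter, a stricter filter (a mean of at least 50 counts and 1 CPM in 3 libraries), a least absolute log2 fold change of 1, all 24 libraries in 1 model, the tag as a replicate block, each replicate left out in turn, and sets of the top 5% by amino acid share. After the headers and values were seen, these were joined by fits within set B, the set as a covariate, a fit of treatment by set, tags left out of both treatments, medians of the passing lists in single pairs of libraries, and the fit without the ribosome-free tag 4 library labelled halofuginone. Log2 ratios of single pairs of libraries used a prior count of 2. List medians by pair covered only tested members with a mean of at least 5 CPM across the 24 libraries, so fewer genes than camera did.

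The steps were tested on simulated counts drawn from the real means and library sizes with known changes. Of genes changed 4-fold edgeR recovered 62.1% in total RNA (12790 genes in that step), 59.1% in light polysomes (12438), 50% in heavy polysomes (12055), 25.8% in heavy against ribosome-free RNA of vehicle cells (12038), 4.55% in heavy relative to total RNA (13044) and 0% in ribosome-free RNA (11792) and in heavy relative to ribosome-free RNA (12762). Of genes changed 2-fold it recovered 0% in total RNA and 2.99% in heavy polysomes. The simulated libraries were unpaired, so these shares do not hold for fits with the tag as a block. Each gene was drawn independently, so no simulated library departed across many genes together, as the set A halofuginone library of total RNA did. The shares may thus overstate recovery in the real data. The full fit of total RNA called 0 genes, while 3961 genes called within set B had an absolute log2 change of at least 1 there. In simulated set B of total RNA edgeR recovered 100% at both sizes (13074 genes). The set B fit used libraries of the same depth as the full fit of total RNA, so depth limited the shares in total RNA less than the spread between libraries did.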

Results

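The study profiled NIH/3T3 cells, an established line of mouse embryonic fibroblasts, after 24 h with halofuginone or with PBS as vehicle. Halofuginone inhibits Eprs, the enzyme that charges the tRNAs for glutamate and proline, and does so at the proline site. RNA was sequenced from whole cells (total RNA) and from pools of polysome gradient fractions, in which mRNAs separate by the number of ribosomes they carry. The ribosome-free pool holds mRNA on no ribosome together with single ribosomal subunits, the light pool holds mRNAs on few ribosomes, and the heavy pool holds mRNAs on more than 5. With 2 treatments and 4 kinds of RNA there were 8 groups of 3 libraries, 24 in all.

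Library depth lay between 10.3 and 25 megacounts (counts assigned to genes, the unit of all depths given here). In total RNA the 3 vehicle libraries held 18.2, 23.2 and 17.5 and the 3 halofuginone libraries 22.0, 22.9 and 25. The ribosome-free pools held 17.4, 10.3 and 11.1 in vehicle and 17.5, 11.9 and 10.5 with halofuginone. The light pools held 20.6, 17.4 and 14.5 in vehicle and 21.6, 15.5 and 14.5 with halofuginone. The heavy pools held 22.5, 22.0 and 13.4 in vehicle and 21.1, 18.9 and 16.2 with halofuginone. Mitochondrially encoded RNAs took 8.69% to 34.9% of the counts in ribosome-free pools, 2.41% to 7.71% in light pools, 0.276% to 0.746% in heavy pools and 2.23% to 4.17% in total RNA. Of the markers of other cell types fixed in advance, 0 of 5 epithelial, 0 of 6 leukocyte and 0 of 5 endothelial genes reached 5 CPM in total RNA, and 2 of 5 adipocyte genes did. Those were Lpl, at 173 CPM in vehicle, and Fabp4, at 11 CPM in vehicle and 2.30 CPM with halofuginone.

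The column headers of the count table divide the libraries into 2 sets. Set A holds 8 libraries, 1 of each group and the first of each trio above. Its headers carry a date-like tag, pool gradient fractions 1 to 2, 3 to 6 and 7 to 11, and name a halofuginone dose of 50 nM where the sample labels give 100 nM. Set B holds the other 16 libraries, which pool fractions 1 to 5, 6 to 13 and 14 to 21 and carry tag 2 together with tag 3 in total RNA or tag 4 in the pools. Fractions were taken to be numbered from the top of the gradient. The design text calls the triplicates biological, but nothing ties a tag to a separate culture, so p-values measure only the spread between these libraries, which may in part be technical.

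The comparison of total RNA asks which transcripts halofuginone raised or lowered in the cell. Trib3 (chromosome 2, 152337422 to 152344032 in GRCm38), a pseudokinase induced by the transcription factor Atf4 under amino acid stress, averaged 158 ± 112 CPM with halofuginone and 13.8 ± 0.828 CPM in vehicle (SD, n = 3 each). Its 3 halofuginone libraries stood at 29.4 CPM in set A and at 231 and 215 CPM in set B. Eprs itself (chromosome 1, 185363044 to 185428360) averaged 837 ± 428 CPM against 329 ± 20.6 CPM, with 344 CPM in set A and 1076 and 1093 CPM in set B. Col1a1 (chromosome 11, 94936224 to 94953042), the main chain of type I collagen, averaged 615 ± 231 CPM against 1400 ± 193 CPM. Col6a1, a chain of type VI collagen, stood at 595 CPM with halofuginone in set A but at 48.2 and 48.4 CPM in set B, against 737 ± 41.4 CPM in vehicle.

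Across all 3 libraries per group, edgeR's quasi-likelihood test called 0 of 13020 genes at a Benjamini-Hochberg adjusted p under 0.05, with 2292 genes at an unadjusted p under 0.05 (1455 higher, 837 lower) and 515 genes called by DESeq2 (296 higher, 219 lower). The smallest adjusted p in edgeR was 0.267. Many genes shared that value, up to an unadjusted edgeR p of at least 0.03065 (Col1a2), so it does not mark the top of a ranking. Of the genes fixed in advance it was held by Trib3 (log2 fold change 3.52 ± 0.75 SE), Ddit3 (2.54 ± 0.70), which encodes a stress-induced transcription factor, Eprs (1.35 ± 0.43), Asns (0.95 ± 0.27), the asparagine synthetase gene, Col1a1 (-1.19 ± 0.29), Col1a2 (-0.84 ± 0.30) and Col3a1 (-1.91 ± 0.65). Atf4 had a log2 fold change of 0.47 ± 0.22 (edgeR adjusted p = 0.310), Fn1, the fibronectin gene, 0.21 ± 0.17 (0.485), and the matrix gene Ltbp2 -1.29 ± 0.48 (0.272). The heparan sulfate editing enzyme Sulf1 and the smooth muscle actin Acta2 had values of -0.99 ± 0.80 and -0.47 ± 1.18. Without the set A halofuginone library edgeR called 8246 genes, and with the set as a covariate it called 6.

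As groups, 13 of 21 gene lists ranked above or below the other genes in total RNA (camera, adjusted p under 0.05). None of them kept that call with an estimated correlation, in this comparison or in any other, and the smallest adjusted p with an estimated correlation was 0.407 in total RNA. The 37 measured genes of the ATF4 and amino acid response had a median log2 fold change of 1.49, and 36 of them were above 0 (camera adjusted p = 4.92e-21, but adjusted p = 0.407 with an estimated correlation). Over all genes none of the 37 passed edgeR's test, while 33 were higher when adjusted over the list alone; the member with the smallest p was Vldlr, a lipoprotein receptor, at 2.37 ± 0.45 (SE). The 20 cytosolic aminoacyl-tRNA synthetases had a median of 0.92 with 19 above 0 (camera adjusted p = 1.4e-07, adjusted p = 0.407 with an estimated correlation; 12 higher adjusted over the list alone). The 12 mRNAs with regulatory upstream reading frames had a median of 1.10, among them Atf5 at 1.61 ± 0.41 (camera adjusted p = 0.00381, adjusted p = 0.407 with an estimated correlation; 5 higher and 1 lower adjusted over the list alone). The 10 snoRNA host and other noncoding RNAs were all above 0, with a median of 1.69 and Snhg8 at 1.09 ± 0.18 (camera adjusted p = 2.05e-06, adjusted p = 0.407 with an estimated correlation).

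On the lower side of total RNA 7 lists passed, among them lipid and matrix genes. All 22 cholesterol synthesis genes were below 0, with a median of -1.56 and Idi1, an enzyme of isoprenoid synthesis, at -2.66 ± 0.69 (camera adjusted p = 1.53e-11, adjusted p = 0.407 with an estimated correlation). The 20 collagens had a median of -1.13, with 3 above 0 and Col4a5 at -1.12 ± 0.25 (camera adjusted p = 2.21e-07, adjusted p = 0.407 with an estimated correlation; 5 lower adjusted over the list alone). The 27 non-collagen matrix proteins had a median of -0.90 and the collagen-binding proteoglycan Lum a value of -2.40 ± 0.40 (camera adjusted p = 5.61e-06, adjusted p = 0.407 with an estimated correlation). Medians were -0.53 for the 19 genes of collagen modification, -0.74 for the 25 mitosis genes, -0.93 for the 14 interferon genes and -0.50 for the 19 inflammatory genes (camera adjusted p = 0.000197, 8.76e-06, 4.47e-05 and 0.00697, each lost at an adjusted p of 0.407 or more with an estimated correlation). Smaller shifts passed for p53 targets (median 0.39, adjusted p = 0.0111) and ribosomal proteins (median 0.19, adjusted p = 0.00932), where the estimated correlation gave adjusted p of 0.407 and 0.823. By single pairs of libraries, over members with a mean of at least 5 CPM across the 24 libraries, 9 of the 13 lists had medians in the direction of their call in all 3. The upstream reading frame mRNAs (-0.07), mitosis genes (0.02) and p53 targets (-0.09) went the other way in set A, and ribosomal proteins (-0.09) in the third pair. The 8 lists that did not pass included the TGF-beta and contractile genes (median -0.27) and DNA replication, whose median of -0.02 turned to 0.02 under another scaling.

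Because the halofuginone libraries of total RNA parted by set, the effect was also tested within set B alone, a choice made after the headers and values had been seen. There edgeR called 9337 of 13334 genes, 4419 higher and 4918 lower, from 2 libraries per group. Trib3 rose by 3.94 ± 0.09 on the log2 scale (edgeR adjusted p = 1.3e-07) and Slc7a11, the cystine transporter, by 4.09 ± 0.11. Ddit3 rose by 3.24 ± 0.12, Eprs by 1.71 ± 0.08, Asns by 1.25 ± 0.07, Atf4 by 0.74 ± 0.07 and Fn1 by 0.28 ± 0.09 (edgeR adjusted p = 0.0265 for Fn1 and 5.13e-05 or below for the others). Col1a1 had a log2 fold change of -1.5 ± 0.11, Col1a2 of -1.24 ± 0.10 and Col3a1 of -3.25 ± 0.11. Ltbp2 stood at -2.14 ± 0.08, Acta2 at -1.27 ± 0.08 and Sulf1 at -1.26 ± 0.28, and all 6 fell (edgeR adjusted p of 0.00414 or below). Among the genes with the largest rises were the secreted carbonic anhydrase Car6 (7.82 ± 0.12) and Als2cl (9.32), and among those with the largest falls the haptoglobin gene Hp (-8.97 ± 0.20) and Aox3 (-8.27).

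Within set B, 36 of the 38 measured ATF4 response genes rose and none fell, and 18 of 20 aminoacyl-tRNA synthetases rose while 1 fell (camera adjusted p = 2.49e-36 and 8.15e-09, but adjusted p = 0.105 and 0.263 with an estimated correlation). All 22 cholesterol genes fell, with Nsdhl at -4.76 ± 0.09 (camera adjusted p = 1.6e-42, adjusted p = 0.0888 with an estimated correlation). All 25 mitosis genes fell, with the cyclin Ccnb2 at -2.72 (camera adjusted p = 1e-16, adjusted p = 0.105 with an estimated correlation). Of 20 collagens 16 fell and 3 rose, with Col6a1 at -3.94 ± 0.08, and of 27 other matrix genes 21 fell and 3 rose, with Tgfbi at -4.87 ± 0.29. Of 19 collagen-modifying genes 16 fell and 1 rose, with the crosslinking enzyme Lox at -3.69 ± 0.12. Members of the TGF-beta list went both ways, with 9 up and 13 down (camera adjusted p = 0.528), and Tgfb3 stood at -2.26. Of the snoRNA host list 8 of 10 rose and none fell, with Snhg1 at 3.61 ± 0.09, while ribosomal protein genes split into 23 up and 27 down of 78. Of 14 interferon genes 13 fell, and of 19 inflammatory genes 13 fell and 5 rose. Of 19 p53 targets 13 rose and 2 fell, and of 34 oxidative phosphorylation genes 24 fell and 4 rose (camera adjusted p = 4.3e-05, 0.0131, 0.00461 and 0.0456, none held with an estimated correlation). Of 21 ER chaperone genes 10 rose and 3 fell, with the chaperone Hspa5 at 2.10, and of 27 autophagy genes 17 fell and 4 rose (camera adjusted p = 0.0707 and 0.244).

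The set B values carry 2 limits. The 2 halofuginone libraries of total RNA in set B were closer to each other than any other pair of one group, with a mean chi-square per gene of 3.12 where the next lowest was 21.1. The spread behind these p-values may be technical. In set A, with 1 library per treatment and so no test, the median log2 ratio was 0.19 for the ATF4 list against 1.97 and 1.94 in the tag 2 and tag 3 pairs. For the cholesterol list it was -0.45 against -3.31 and -3.12.

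**Figure D1:**
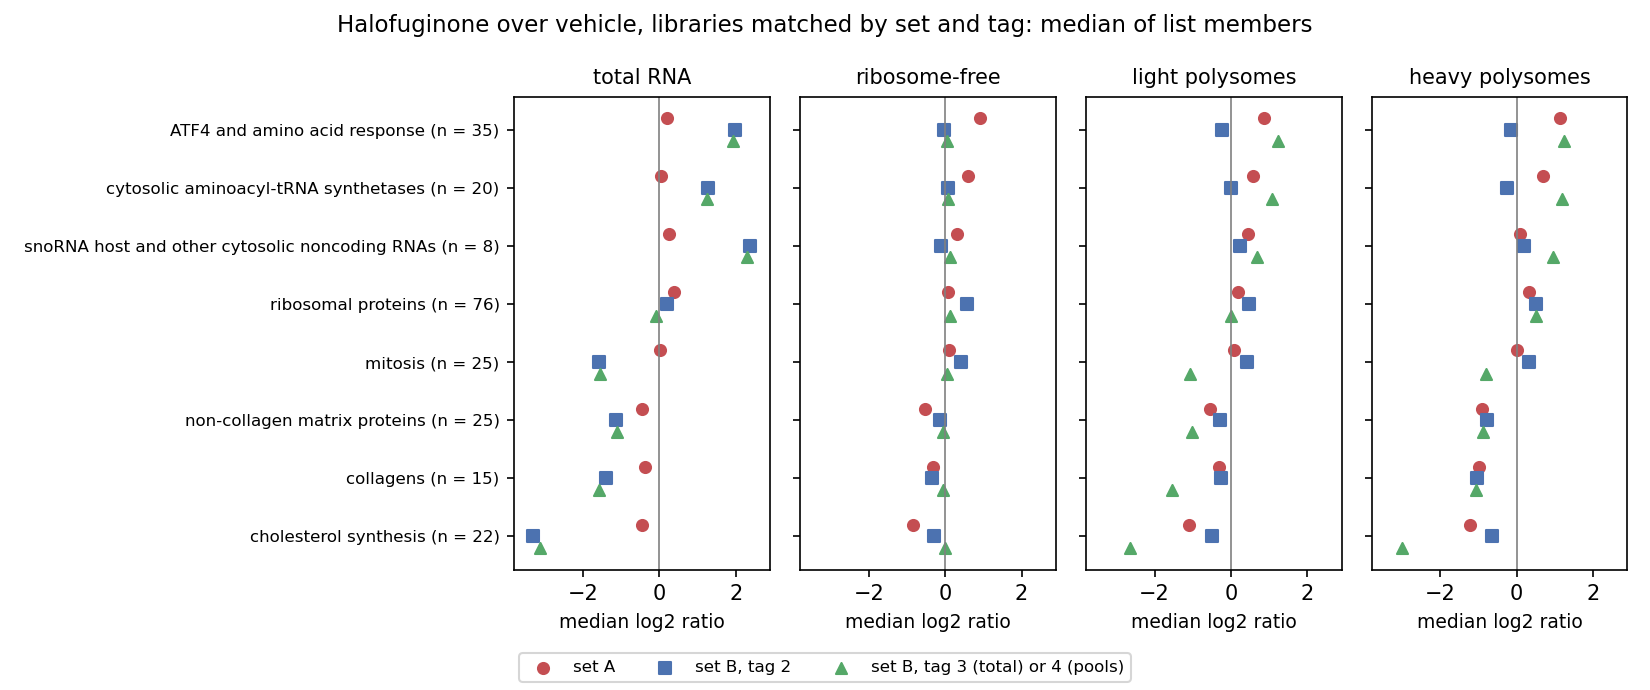
Median log2 ratio of halofuginone over vehicle for members of the gene lists named on the panels, with 1 point for each pair of libraries matched by set and tag in total RNA and each gradient pool. In total RNA the set A point of the ATF4 list lies at 0.19 and the set B points at 1.97 and 1.94.

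The comparison within heavy polysomes asks which mRNAs changed on the most heavily translated part of the gradient. Lox (chromosome 18, 52516067 to 52529867) averaged 340 ± 115 CPM with halofuginone and 1535 ± 751 CPM in vehicle (SD, n = 3 each), and Col6a1 (chromosome 10, 76708792 to 76726168) 139 ± 69.5 against 551 ± 273 CPM. Lss, the cholesterol enzyme lanosterol synthase (chromosome 10, 76531588 to 76557138), averaged 64.9 ± 21.9 against 205 ± 15.3 CPM. Slc7a11 (chromosome 3, 49892526 to 50443614) averaged 35.8 ± 31 against 3.93 ± 1.48 CPM, and Trib3 340 ± 305 against 75.9 ± 74 CPM.

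In heavy polysomes edgeR called 0 of 12222 genes at an adjusted p under 0.05, with 754 at an unadjusted p under 0.05 (236 higher, 518 lower) and 78 called by DESeq2 (29 higher, 49 lower). Within set B edgeR also called 0, with 502 at an unadjusted p under 0.05. Log2 fold changes were -2.18 ± 0.44 (SE) for Lox, -1.66 ± 0.31 for Lss, 3.20 ± 0.73 for Slc7a11 and -1.31 ± 0.30 for the elastic fibre protein Emilin1, all at an edgeR adjusted p of 0.767. Col6a1 stood at -1.98 ± 0.50 (edgeR adjusted p = 0.792), Trib3 at 2.17 ± 0.93 (0.805), Col1a1 at -1.63 ± 0.78 (0.827) and Eprs at 1.12 ± 0.55 (0.834). The remaining genes fixed in advance also missed the threshold: Ddit3 at 1.67 ± 0.92, Asns at 0.86 ± 0.50, Atf4 at 0.71 ± 0.55 and Col3a1 at -1.83 ± 1.05. Ltbp2 stood at -1.23 ± 1.01, Col1a2 at -0.81 ± 0.56, Sulf1 at -0.83 ± 1.29, Fn1 at -0.06 ± 0.81 and Acta2 at 0.54 ± 1.39. With the tag as a block, a fit the pairing check allowed for the pools, edgeR called 2 genes, both higher and both outside the naming rule: Car6 (6.26 ± 0.22, adjusted p = 0.00127) and Avil, an actin-binding protein (5.45 ± 0.28, adjusted p = 0.00702). Car6 averaged 70.1 ± 68.8 CPM with halofuginone and 0.893 ± 0.859 CPM in vehicle.

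**Figure D2:**
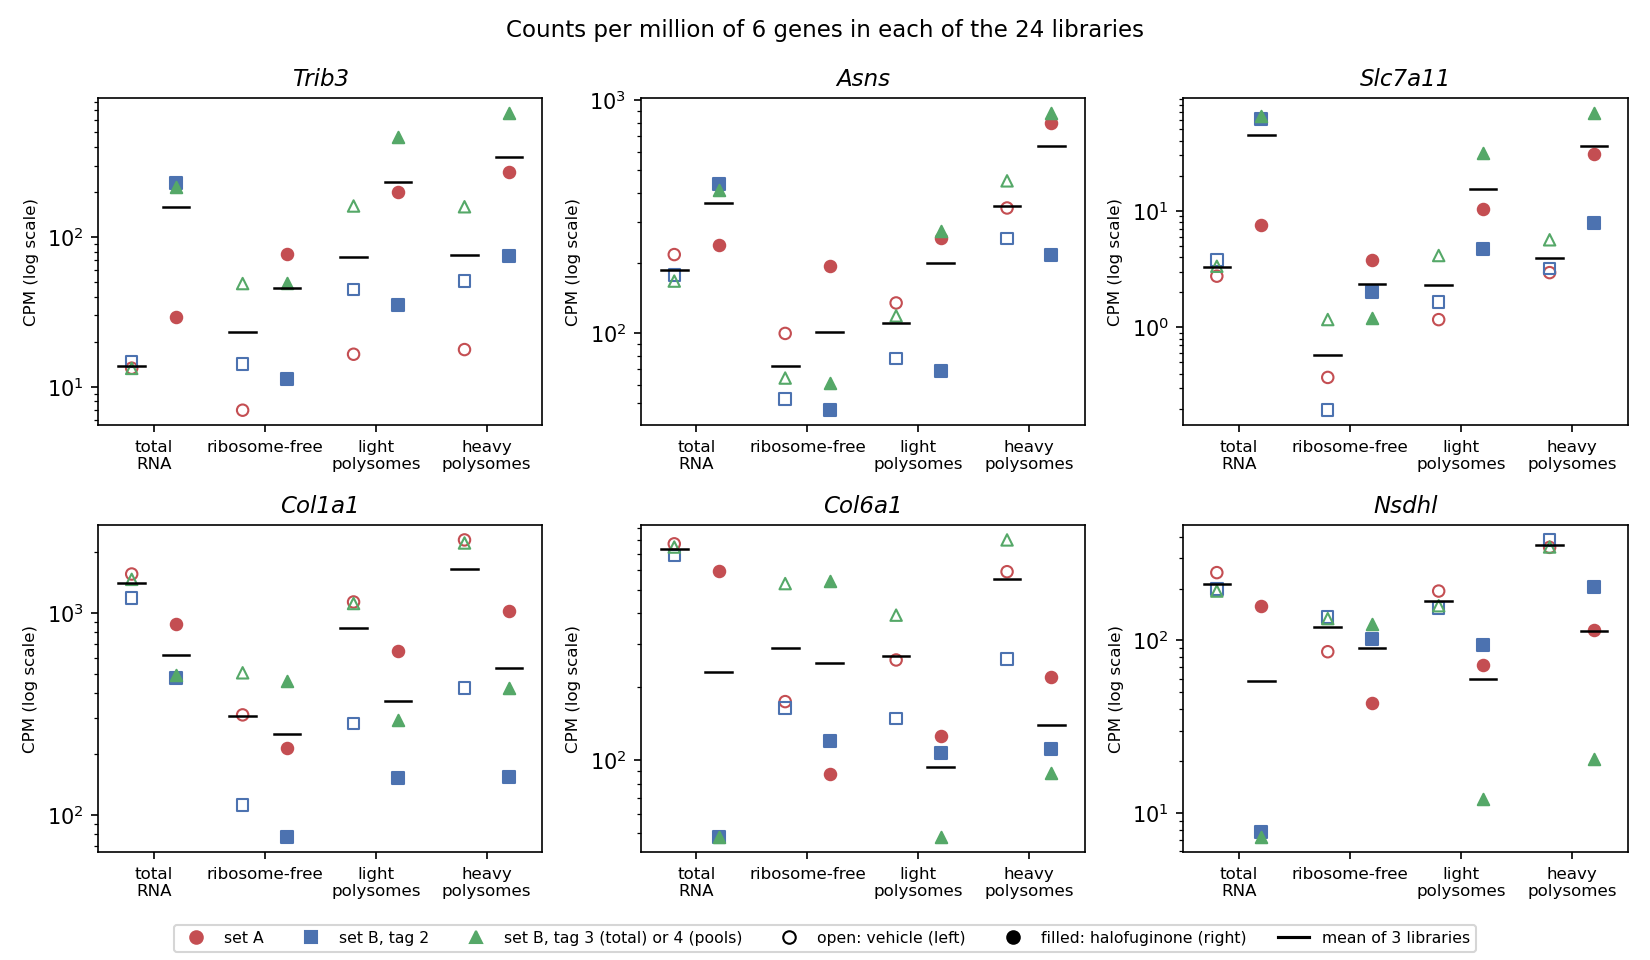
CPM of Trib3, Asns, Slc7a11, Col1a1, Col6a1 and Nsdhl in each of the 24 libraries on a log axis, with open points for vehicle, filled points for halofuginone and a bar at each group's mean. In total RNA Trib3 with halofuginone stands at 29.4 CPM in set A and at 231 and 215 CPM in set B.

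In heavy polysomes 15 of 21 lists passed camera, none with an estimated correlation. The collagens were all below 0, with a median of -1.36 over 20 genes (camera adjusted p = 5.46e-10, adjusted p = 0.340 with an estimated correlation). Over the 15 collagens with a mean of at least 5 CPM across the 24 libraries, the medians by pair were -0.98 in set A, -1.03 for tag 2 and -1.07 for tag 4. The 28 other matrix genes had a median of -0.98 and the 20 collagen-modifying genes of -0.55 (camera adjusted p = 1.62e-08 and 1.7e-06), with 2 members each lower adjusted over the list alone. All 22 cholesterol genes were below 0 with a median of -1.28 (camera adjusted p = 1.9e-24, adjusted p = 0.340 with an estimated correlation). The 36 ATF4 response genes had a median of 0.93 with 34 above 0 (camera adjusted p = 8.33e-14, adjusted p = 0.340 with an estimated correlation). The medians by pair were 1.14 in set A, -0.16 for tag 2 and 1.24 for tag 4. The aminoacyl-tRNA synthetases behaved in the same way, with a median of 0.79 and pair medians of 0.70, -0.27 and 1.18 (camera adjusted p = 0.000133, adjusted p = 0.469 with an estimated correlation).

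Of the 77 ribosomal protein mRNAs 74 were above 0 in heavy polysomes, with a median of 0.43, pair medians of 0.32, 0.52 and 0.51, and Rps14 at 0.71 ± 0.23 (camera adjusted p = 4.35e-16). DNA replication genes had a median of 0.36 with Rfc3 at 0.57 ± 0.23, mitochondrially encoded mRNAs of 0.69 with mt-Cytb at 0.88 ± 0.30, and the snoRNA host list of 0.49 with Snhg8 at 0.83 ± 0.32 (camera adjusted p = 7.38e-05, 0.000174 and 0.00848). Mitochondrially encoded RNAs took only 0.276% to 0.746% of the counts in heavy pools and lay almost wholly outside them in vehicle cells. Their rise there therefore does not show a change in translation. The 14 interferon genes were all below 0, with a median of -0.95 and the RNA sensor Ddx58 at -1.44 ± 0.35, and the 18 inflammatory genes had a median of -0.54 with the cytokine Il6 at -2.03 ± 0.61 (camera adjusted p = 1.25e-07 and 0.000861). Smaller sets passed as well, namely the upstream reading frame mRNAs (median 0.61, Ppp1r15a at 1.81 ± 0.71), the translation factors with TOP mRNAs (median 0.24, Npm1 at 0.66 ± 0.28) and, on the lower side, the nuclear-retained noncoding RNAs (median -0.63, Neat1 at -1.90 ± 0.54), at camera adjusted p of 0.0062, 0.00593 and 0.0102. In heavy polysomes 11 of the 15 lists went with their call in all 3 pairs. The upstream reading frame mRNAs stood at -0.22 in tag 2 against 0.62 and 1.26, with Ppp1r15a at -0.32, and mitochondrial mRNAs at -0.21 in set A against 1.06 and 1.02. The others were the ATF4 list and the synthetases. With an estimated correlation every one of these lists had an adjusted p of at least 0.340. With the block the TGF-beta list passed too, on the lower side (camera adjusted p = 0.0375 in place of 0.165, adjusted p = 0.457 with an estimated correlation).

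The comparison within light polysomes asks the same of mRNAs with few ribosomes. Aldh1l2, a mitochondrial folate enzyme of the ATF4 list (chromosome 10, 83487450 to 83534140), averaged 122 ± 104 CPM with halofuginone and 20.3 ± 4.95 CPM in vehicle (SD, n = 3 each). The cholesterol enzyme Pmvk averaged 21.7 ± 9.28 against 61.4 ± 12.2 CPM, and the laminin chain Lama4 21.2 ± 10.8 against 57.4 ± 25.8 CPM. Their log2 fold changes were 2.59 ± 0.59, -1.5 ± 0.37 and -1.44 ± 0.45 (SE), each at an edgeR adjusted p of 0.981. In this pool edgeR called 0 of 12632 genes, with 540 at an unadjusted p under 0.05 and 39 called by DESeq2 (25 higher, 14 lower). In simulated light polysomes, which held genes with known changes, DESeq2 also made 37 calls among unchanged genes. Some of the 39 may thus be false, though 37 is not the count expected without any change. Within set B edgeR called 0, with 400 there at an unadjusted p under 0.05. With the tag as a block edgeR called 3 genes, all higher and named after their values were seen: Car6 (6.44), Gdap1l1 (4.14) and 1700006H21Rik (7.99).

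Among the lists, 13 passed camera in light polysomes, none with an estimated correlation (adjusted p of at least 0.476). Cholesterol genes were again all below 0, with a median of -1.07 (camera adjusted p = 2.22e-20). Collagens, other matrix genes and collagen-modifying genes had medians of -0.64, -0.73 and -0.30 (camera adjusted p = 1.99e-05, 2.44e-05 and 0.0176), with Col6a1 at -1.51 ± 0.47 and Lox at -1.43 ± 0.46. The ATF4 list had a median of 0.87 with 34 of 38 genes above 0 and the synthetases a median of 0.60 with Lars at 1.05 ± 0.44 (camera adjusted p = 5.05e-09 and 1.29e-05). Pair medians of the ATF4 list were 0.88 in set A, -0.22 for tag 2 and 1.22 for tag 4. The synthetases (-0.01 for tag 2) and ribosomal proteins (-0.01 for tag 4) also had 1 pair against their call, and the other 10 lists had none. DNA replication genes (median 0.35, Cdt1 at 0.65 ± 0.30), ribosomal proteins (0.18, Rpl14 at 0.46 ± 0.26), the snoRNA host list (0.50, Snhg8 at 0.82 ± 0.29) and mitochondrial mRNAs (0.65, mt-Nd4 at 0.68 ± 0.41) ranked higher, at camera adjusted p of 0.000117, 0.00132, 0.00147 and 0.0365. Interferon genes (median -0.97, Irf1 at -0.97 ± 0.37), inflammatory genes (-0.60, Il6 at -1.54 ± 0.53) and nuclear-retained RNAs (-0.62, Neat1 at -1.73 ± 0.51) ranked lower, at 3.33e-05, 8.25e-05 and 0.0176, and the last of these calls ended with the block (camera adjusted p = 0.0861). The fixed genes Trib3 (1.66 ± 0.99), Ddit3 (0.95 ± 0.67), Eprs (0.86 ± 0.43), Asns (0.85 ± 0.50) and Atf4 (-0.24 ± 0.28) missed the threshold. So did Col1a1 (-1.21 ± 0.65), Col3a1 (-1.40 ± 0.90), Col1a2 (-0.48 ± 0.40), Ltbp2 (-0.70 ± 0.83), Fn1 (0.31 ± 0.60) and Acta2 (0.29 ± 1.65).

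The comparison within the ribosome-free pool asks which untranslated mRNAs differed. Il6 (chromosome 5, 30013114 to 30019981) averaged 2.52 ± 0.948 CPM in libraries labelled halofuginone and 10.4 ± 3.4 CPM in vehicle (SD, n = 3 each), a log2 fold change of -2.04 ± 0.45 (SE; edgeR adjusted p = 1). Slc7a11 stood at 2 ± 0.78, the unfolded protein response factor Xbp1 at -0.92 ± 0.39, Trib3 at 0.98 ± 0.87, Eprs at 0.41 ± 0.34 and Col1a1 at -0.31 ± 0.76, and the other fixed genes between -0.41 (Ltbp2) and 0.49 (Asns). Here edgeR called 0 of 11960 genes and DESeq2 0, with 30 at an unadjusted p under 0.05 in edgeR, and within set B edgeR called 0, again with 30 at an unadjusted p under 0.05. These are fewer than 0.05 of the tested genes, the share expected without any change. The unpaired test was thus too cautious in this pool, and its count of 0 does not show that nothing changed. With the tag as a block, 1002 genes had an unadjusted p under 0.05 and edgeR called 15 genes, 12 higher and 3 lower. Among them were Car6 (4.64), the skin adhesion protein Cdsn (2.71), the proline synthesis enzyme Pycr1 (1.05), Il6 (-2.03, edgeR adjusted p = 0.00726) and Thbs1, thrombospondin (-0.78). These names were taken after their values were seen.

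In the ribosome-free pool 11 lists passed camera, and none with an estimated correlation (adjusted p of at least 0.338). The ATF4 list had a median of 0.39 with 32 of 36 genes above 0, the synthetases of 0.25 with Wars at 0.80 ± 0.48, and ribosomal proteins of 0.23 with Rps12 at 0.38 ± 0.41 (camera adjusted p = 3.94e-10, 0.000123 and 3.8e-08). The ATF4 median came from set A, where the pair stood at 0.92, while the tag 2 and tag 4 pairs stood at -0.03 and 0.04. In the tag 4 pair TOP translation factors (-0.03), DNA replication genes (-0.07) and ER chaperones (0.00) did not go with their calls, and 7 of the 11 lists did so in all 3 pairs. Inflammatory genes had a median of -0.48, cholesterol genes of -0.32 with Fdps at -0.80 ± 0.44, ER chaperones of -0.16, matrix genes of -0.18 and collagens of -0.15 with Col12a1 at -0.92 ± 0.81 (camera adjusted p = 2.34e-10, 1.88e-08, 0.0042, 0.0187 and 0.0236). Mitosis genes (median 0.22, Cenpe at 0.57 ± 0.40), DNA replication genes (0.14, Mcm7 at 0.56 ± 0.49) and TOP translation factors, with Eef1g at 0.38 ± 0.36, also passed on the higher side (camera adjusted p = 0.00114, 0.0233 and 0.0223). With the block 2 more lists passed, collagen modification (camera adjusted p = 0.0473) and the snoRNA host list (0.0123), with adjusted p of 0.769 and 0.578 at an estimated correlation. The median of the p53 targets, which did not pass, was -0.01 and turned to 0.02 under another scaling, as did that of the ER chaperones in heavy polysomes, from -0.01 to 0.06.

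The difference of differences between heavy polysomes and total RNA asks whether mRNAs changed on heavy polysomes by more or less than in the cell. As a list, the ATF4 response genes ranked below other genes in this difference, with a median of -0.54 and 4 of 38 genes above 0 (camera adjusted p = 1.58e-08, adjusted p = 0.637 with an estimated correlation). The member with the smallest p was the cationic amino acid transporter Slc7a3, at -2.13 ± 0.78 (SE, n = 3 libraries per group). All 10 RNAs of the snoRNA host list, most of them noncoding transcripts whose introns hold snoRNAs, were below 0 with a median of -1.40 and Snhg12 at -2.36 ± 0.87 (camera adjusted p = 3.84e-10, adjusted p = 0.462 with an estimated correlation). All 25 mitosis genes were above 0 with a median of 0.68 and the checkpoint kinase Bub1 at 0.87 ± 0.55 (camera adjusted p = 2.43e-09). Of 77 ribosomal protein genes 73 were above 0, with a median of 0.28 and Rps4x at 0.51 ± 0.41 (camera adjusted p = 1.58e-08). With an estimated correlation both had an adjusted p of at least 0.462. DNA replication genes (0.41, Gins2 at 0.82 ± 0.44), mitochondrial mRNAs (0.53, mt-Nd6 at 2.41 ± 0.96), oxidative phosphorylation genes (0.20, Ndufa1 at 0.61 ± 0.43) and cholesterol genes (0.20, Idi1 at 1.61 ± 1.34) ranked higher too, at camera adjusted p of 5.83e-07, 0.000119, 0.00293 and 0.0099. For the mitochondrial mRNAs, scarce in heavy pools, this again does not show a change in translation. The p53 targets (Btg2 at -0.94 ± 0.51), ER chaperones (Xbp1 at -0.60 ± 0.38) and nuclear-retained RNAs (Kcnq1ot1 at -2.06 ± 0.81) ranked lower, each at a camera adjusted p of 0.0378. None of these lists passed with an estimated correlation either (camera adjusted p of at least 0.462). The collagens did not pass, and Col1a1 stood at -0.43 ± 0.92.

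Of these 11 lists only DNA replication, p53 targets and the snoRNA host list went with their call in all 3 pairs of libraries, and for the last of these set A stood at -0.07 against -2.18 and -1.32. With halofuginone the tags did not pair total RNA with heavy polysomes. Same-tag correlations were 0.281, -0.382 and 0.603, each below the highest with another tag (0.380, 0.631 and 0.631). The matching behind these values by pair is therefore nominal. In set A 7 lists went the other way. The ATF4 list had a median difference of 0.96 there against -1.84 for tag 2 and -0.74 for the third pair, mitosis genes -0.07 against 1.77 and 0.74, ribosomal proteins -0.09 against 0.30 and 0.67, and mitochondrial mRNAs -0.18 against 1.19 and 0.39. Cholesterol genes stood at -0.79 in set A, 2.39 for tag 2 and 0.10 for the third pair, so under this matching their rank rests on tag 2. Oxidative phosphorylation genes (-0.02) and ER chaperones (0.06) were the others, and ER chaperones were lower in tag 2 alone, while nuclear-retained RNAs were higher in tag 2 (0.70).

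For single genes this difference was not resolved, and fewer than 0.05 of the tested genes had an unadjusted p under 0.05. In this comparison edgeR called 0 of 13459 genes, with 128 at an unadjusted p under 0.05, while DESeq2 called 1, P2rx7, an ATP-gated channel, at -4.64 (DESeq2 adjusted p = 0.0350). In simulated counts of this comparison, which held genes with known changes, DESeq2 also made 13 calls among unchanged genes. A single DESeq2 call may thus be false, though 13 is not the count expected without any change. P2rx7 averaged 21.9 CPM in total RNA with halofuginone against 3.99 in vehicle, and 0.87 against 3.89 CPM in heavy polysomes; it was named after its values were seen. Without the set A vehicle libraries edgeR called 1 gene, the processed pseudogene Smt3h2-ps, and within set B it called 0, with 1542 at an unadjusted p under 0.05. The fixed genes had differences of -1.33 ± 1.26 (Trib3), -0.85 ± 1.25 (Ddit3), -0.21 ± 0.76 (Eprs), -0.08 ± 0.63 (Asns) and 0.26 ± 0.66 (Atf4), all at an edgeR adjusted p of 1. The matrix genes among them and Acta2 had 0.05 ± 0.71 (Col1a2), 0.09 ± 1.33 (Col3a1), -0.26 ± 0.96 (Fn1), 0.06 ± 1.24 (Ltbp2), 0.17 ± 1.68 (Sulf1) and 1.02 ± 2.02 (Acta2), again at an edgeR adjusted p of 1.

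The same difference against the ribosome-free pool, which comes from the same gradients, asks whether mRNAs moved between no ribosome and many. As a list, the 22 cholesterol genes ranked below other genes in this difference, with a median of -0.94, 1 gene above 0 and Dhcr7 at -1.16 ± 0.50 (camera adjusted p = 5.3e-21). By pair the median difference was -0.40 in set A, -0.39 for tag 2 and -2.89 for tag 4, so its size rests on tag 4. The collagens were all below 0 with a median of -0.83 and Col18a1 at -1.89 ± 1.02, and other matrix genes had a median of -0.74 with Lama4 at -1.58 ± 0.53 (camera adjusted p = 5.16e-08 and 3.57e-07). Of 38 ATF4 response genes 37 were above 0, with a median of 0.63 and Aldh1l2 at 1.64 ± 1.04, and all 20 synthetases were above 0 with a median of 0.56 (camera adjusted p = 4.16e-07 and 0.00371). The pairs of libraries were uneven here. The ATF4 list had a median difference of 0.25 in set A, -0.08 for tag 2 and 1.24 for tag 4, and the synthetases 0.11, -0.35 and 1.15. The rise thus rests mainly on the tag 4 pair, whose ribosome-free libraries are in doubt. The estimated correlation gave these lists, and those named below, adjusted p of at least 0.345. Further lists passed with higher values for upstream reading frame mRNAs (0.75, Ppp1r15a at 1.35 ± 1.00), mitochondrial mRNAs (0.86, mt-Cytb at 1.14 ± 0.58), ribosomal proteins (0.28, Rps24 at 0.47 ± 0.50) and DNA replication (0.30, Rfc4 at 0.53 ± 0.45). The mitochondrial mRNAs lay almost wholly outside heavy polysomes in vehicle cells, so their value does not show a move onto ribosomes. Lists that passed with lower values were interferon genes (-0.77, Irf7 at -2.78 ± 1.22), collagen modification (-0.37, Pcolce at -1.26 ± 0.58), mitosis (-0.19, Cenpe at -0.64 ± 0.59) and nuclear-retained RNAs (Meg3 at -1.69 ± 0.99). Of the 13 lists 6 went with their call in all 3 pairs, namely collagens, other matrix genes, collagen modification, mitosis, cholesterol synthesis and nuclear-retained RNAs. In tag 2 the upstream reading frame mRNAs (-0.20), ribosomal proteins (-0.06) and DNA replication genes (-0.09) went the other way, and in set A mitochondrial mRNAs (-0.97), interferon genes (0.13) and, again, DNA replication genes (-0.01). With the block the TGF-beta list (camera adjusted p = 0.0154) and the p53 targets (0.0334) passed as well, both at an adjusted p of 0.255 with an estimated correlation.

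For single genes against the ribosome-free pool, edgeR called 0 of 13053 genes and DESeq2 0, with 53 at an unadjusted p under 0.05 in edgeR. With the block these were 71, with 0 called. Both counts are fewer than 0.05 of the tested genes, so a count of 0 does not show that nothing changed. Within set B edgeR called 1, Smt3h2-ps. The library labelled halofuginone in the ribosome-free tag 4 pair differed little from its vehicle partner, and without it 9 lists passed in place of 13. The synthetases (camera adjusted p = 0.0946), ribosomal proteins (0.878), DNA replication genes (0.730, at a median of -0.16) and nuclear-retained RNAs (0.730) lost their calls, while the ATF4 list still passed at a median of 0.49 (camera adjusted p = 3.28e-07, adjusted p = 0.585 with an estimated correlation). That fit still holds the other tag 4 libraries. Eprs stood at 0.81 ± 0.70, Atf4 at 0.85 ± 0.73, Ddit3 at 1.32 ± 1.18, Asns at 0.46 ± 0.84, Trib3 at 1.29 ± 1.37, Col1a1 at -1.25 ± 1.17 and Col1a2 at -0.65 ± 0.83. Col3a1 stood at -1.53 ± 1.51, Fn1 at 0.10 ± 1.2, Ltbp2 at -0.75 ± 1.28, Sulf1 at -0.94 ± 1.81 and Acta2 at 0.19 ± 2.68, and all 12 had an edgeR adjusted p of 1.

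The comparison of heavy polysomes with the ribosome-free pool in vehicle cells asks which mRNAs took a larger share of either pool without the inhibitor. The light pool is left out and lists were not corrected for coding length, so a low ratio does not mean that an mRNA carried no ribosome. Mitochondrial transcripts lay almost wholly outside heavy polysomes, with log2 ratios of -8.37 ± 0.85 for mt-Nd1 (mitochondrial genome, 2751 to 3707), -8.42 ± 0.65 for the ribosomal RNA mt-Rnr1 and -9.36 ± 1.42 for the tRNA mt-Ti (SE, n = 3 each, edgeR adjusted p of 0.00282 or below). The mRNA mt-Co2 was called lower too, but no fold is given, as its heavy libraries of set A and tag 4 lay at the floor in both treatments. The snoRNA host Snhg6 stood at -5.50 ± 0.43, the small nuclear RNA Rn7sk at -6.51 ± 1.10, and the imprinted noncoding RNAs Mirg and Rian at -5.46 ± 0.54 and -4.71 ± 0.63, and all 4 were lower in heavy polysomes. The ribosomal protein mRNAs Rps12 (chromosome 10, 23785183 to 23787275) and Rpl39 stood at -4.69 ± 0.51 and -4.14 ± 0.46. Among genes that met the naming rule, the protocadherin Pcdhgc3 (chromosome 18, 37806364 to 37841873) had the largest rise, at 4.20 ± 0.75 (edgeR adjusted p = 0.00484), followed by Ugt1a7c at 3.49 ± 0.50 and Med12, a subunit of the Mediator complex, at 3.46 ± 0.74. Pcdhgc3 and Ugt1a7c each share exons with other genes of their cluster, so that their counts are uncertain.

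In vehicle cells edgeR called 3616 of 12225 genes, 1457 higher and 2159 lower in heavy polysomes. Of 77 ribosomal protein mRNAs 57 were lower and none higher, with a median of -2.19 (61 lower adjusted over the list alone; camera adjusted p = 1.99e-20, adjusted p = 0.652 with an estimated correlation). All 9 RNAs of the list of snoRNA hosts and other noncoding RNAs were lower (median -4.46), as were 8 of 8 mitochondrial mRNAs (median -7.27) and 4 of 6 nuclear-retained RNAs (median -2.72), at camera adjusted p of 5.06e-16, 7.11e-14 and 0.000742 (adjusted p of at least 0.0937 with an estimated correlation). Of the 20 aminoacyl-tRNA synthetases 9 were higher and none lower (median 1.06, Iars at 2.14 ± 0.53), and of 20 collagen-modifying genes 9 were higher (median 1.21, Pcolce at 2.43 ± 0.51), at camera adjusted p of 5.22e-05 and 0.000742. Of 28 matrix genes 5 were higher, with Lama4 and Emilin1 both at 2.55, and of 20 collagens 2, with Col16a1 at 2.56 ± 0.53 (camera adjusted p = 0.00464 and 0.0133). Lists of DNA replication (5 higher and 1 lower, Pcna at 2.30 ± 0.50), autophagy (8 and 3, Ctsl at 2.49 ± 0.61), cholesterol synthesis (5 and 1, Acat2 at 1.41 ± 0.36) and TOP translation factors (0 and 7, Pabpc1 at -2.94 ± 0.49) also passed, at camera adjusted p of 0.0116, 0.0272, 0.0315 and 0.0409. With an estimated correlation the synthetases and these collagen, matrix and other lists all had an adjusted p of at least 0.652. The cholesterol and TOP calls also ended with the block, at 0.0503 and 0.0673.

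Several stress mRNAs whose translation is governed by upstream reading frames were lower in heavy polysomes than in the ribosome-free pool of vehicle cells. Atf4 (chromosome 15, 80255184 to 80257541) stood at -2.31 ± 0.49, Ddit3 at -1.84 ± 0.46 and Slc35a4 at -2.19 ± 0.35 (edgeR adjusted p = 0.00917, 0.0171 and 0.00327). Of the 12 mRNAs of that list 6 were lower and 2 higher, one of these being Eprs at 1.22 ± 0.39 (edgeR adjusted p = 0.0434), and the list as such did not pass (camera adjusted p = 0.319). Within the ATF4 list 8 genes were lower, with Nupr1 at -3.47 ± 0.45, and 3 higher, with Phgdh, an enzyme of serine synthesis, at 2.32 ± 0.66 and Asns at 1.46 ± 0.42. The cytokine mRNAs Cxcl1 and Il6 stood at -2.94 ± 0.39 and -2.85 ± 0.46, the mRNAs of the small membrane proteins Cox7c and Sec61b at -2.42 ± 0.47 and -2.96 ± 0.55, and the chaperone Pdia6 at 2.42 ± 0.55. Col1a1 (1.60 ± 0.73, edgeR adjusted p = 0.127), Col3a1 (1.81 ± 0.96), Col1a2 (1.36 ± 0.61), Ltbp2 (1.40 ± 0.84), Sulf1 (1.15 ± 1.25), Fn1 (1.06 ± 0.83), Trib3 (0.91 ± 0.84) and Acta2 (-1.03 ± 1.54) did not pass. With the block Col1a1 and Col3a1 did, at 1.5 and 1.52 (edgeR adjusted p = 0.0235 and 0.0183). The number of calls in vehicle cells rested on single libraries. Without the tag 2 pair edgeR called 784 genes, without the tag 4 pair 1353, and without the set A pair, which is the fit within set B, 5524. Of the 43 named genes called, 17 were called with each pair left out in turn, among them mt-Nd1, Snhg6, Rps12, Rpl39, Pcdhgc3, Lama4, Emilin1, Nupr1 and Cxcl1. Without the tag 2 pair 26 of the 43 missed the threshold, including Atf4, Ddit3, Asns and Eprs, and without the tag 4 pair 14 did.

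**Figure D3:**
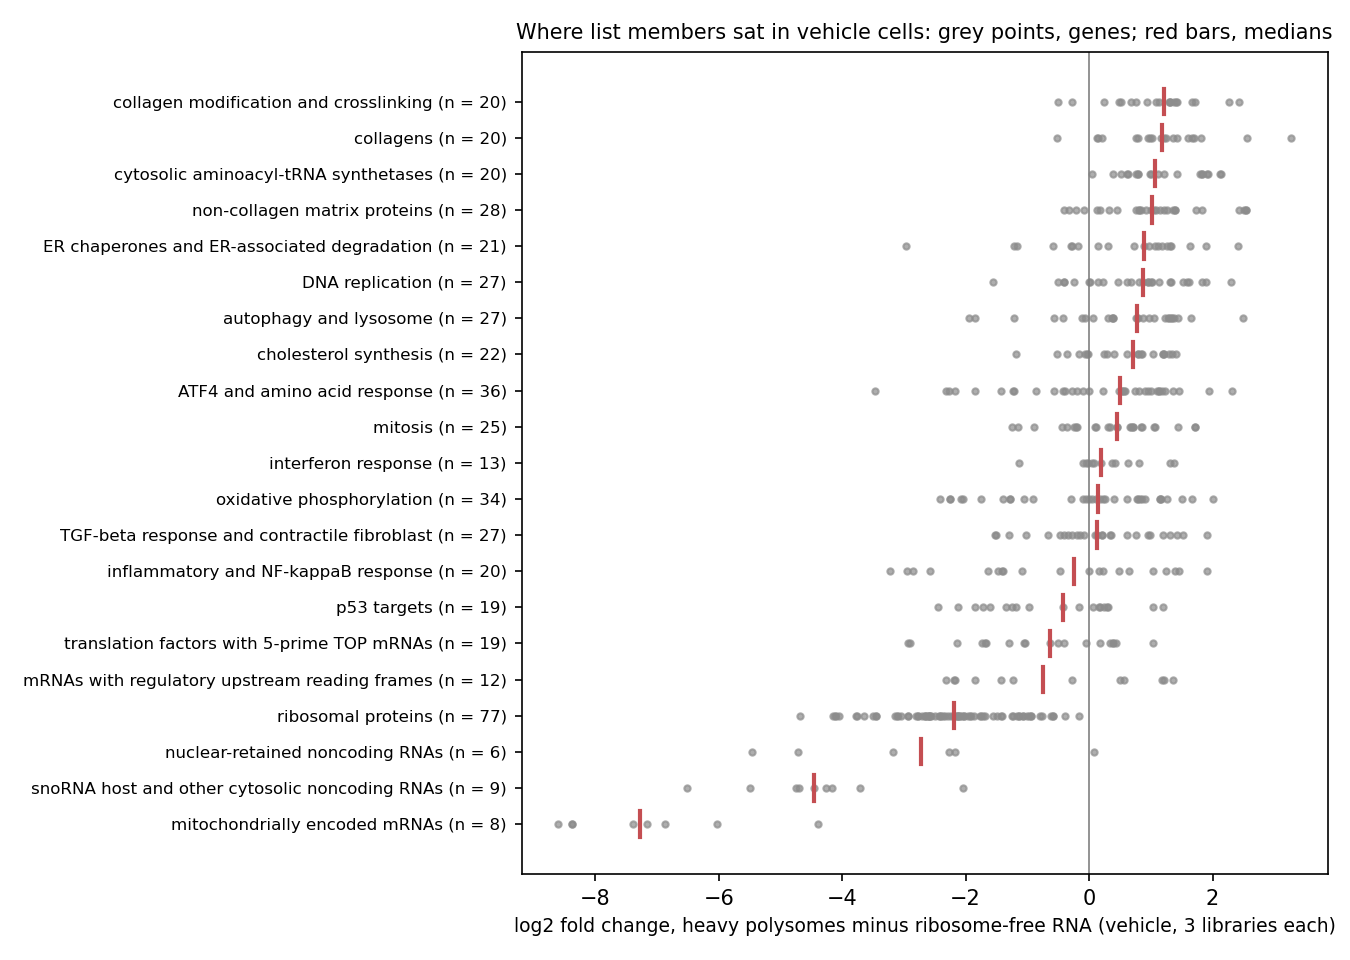
Log2 ratio of heavy polysomes to the ribosome-free pool in vehicle cells for the genes of 21 lists, with a grey point for each gene and a red bar at each list's median. The mitochondrially encoded mRNAs lie lowest, with a median of -7.27, and ribosomal protein mRNAs have a median of -2.19.

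Because the inhibitor blocks the charging of proline tRNA, genes were also compared by the amino acid content of their proteins, taking for each of the 20 amino acids the 10% of genes with the largest share. Proline-rich genes did not stand apart from the rest in any halofuginone comparison tested. Their median log2 fold change differed from that of other genes by -0.04 in total RNA (camera adjusted p = 0.945), -0.10 in light polysomes (0.156), -0.05 in heavy polysomes (0.602), -0.02 for heavy polysomes relative to total RNA (0.984) and -0.06 relative to the ribosome-free pool (0.544). With the collagens taken out of the set, the unadjusted camera p was 0.954 in total RNA and 0.405 in heavy polysomes. In vehicle cells the difference was -0.15 (camera adjusted p = 0.304), and after a correction for GC content and length it was -0.46 (adjusted p = 0.000731). These p-values come from unlike tests, on counts and on fold changes, so the correction alone may not account for the change.

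Lysine-rich and glutamate-rich genes did pass on heavy polysomes. Lysine-rich genes lay 0.23 above the rest there (camera adjusted p = 5.38e-06, adjusted p = 0.417 with an estimated correlation), and 0.15 above in light polysomes (camera adjusted p = 0.00955, adjusted p = 0.420 with an estimated correlation). For heavy polysomes relative to the ribosome-free pool they lay 0.23 above (camera adjusted p = 1.3e-05, adjusted p = 0.0238 with an estimated correlation). Glutamate-rich genes lay 0.12 above in heavy and 0.13 above in light polysomes (camera adjusted p = 0.0458 and 0.0202; adjusted p = 0.417 and 0.0275 with an estimated correlation). After the correction for GC content and length none of these 5 calls held, with adjusted p between 0.106 for lysine in heavy polysomes and 0.469 for lysine in light polysomes. As the corrected test used fold changes and not counts, the loss cannot be credited to the correction alone. Other choices gave corrected calls on heavy polysomes, for lysine and arginine in the top 5% of genes (adjusted p = 0.0354 and 0.0478) and for the same amino acids within set B (both 0.0430). Relative to the ribosome-free pool arginine passed in the top 5% (0.0416) and arginine and, on the lower side, phenylalanine within set B (both 0.0418). In vehicle cells lysine-rich genes lay -0.84 from the rest (camera adjusted p = 5.07e-09, adjusted p = 0.0316 with an estimated correlation), or -0.43 after the correction (adjusted p = 0.00102). Lysine was not alone there, as 6 sets passed camera, the others being cysteine, histidine, methionine, arginine and threonine. After the correction 6 sets passed.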

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

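All tests of explanations in this part were chosen only after the results they bear on had been seen, and the set division was taken from the column headers after the values were known. What the counts over other splits of the samples would mean was also written down only after they were seen.

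An edgeR fit of treatment by set in total RNA put the effect in the set A pair apart from that in set B for 6781 of 13020 genes (3604 above, 3177 below), with 7575 at an unadjusted p under 0.05. Set A has 1 library per treatment, so the error comes from the set B replicates alone, whose biological coefficient of variation in edgeR was 0.0772. As the 2 set B halofuginone libraries are unusually close, the count sets 1 pair against that spread and does not test a replicated difference. The same fit in the ribosome-free, light and heavy pools called 0 genes in edgeR, with 74, 14 and 12 at an unadjusted p under 0.05 and no other tool run. There the coefficient in set B was 0.319, 0.383 and 0.380, so these counts do not show that the pools differ less between sets. Of the 9337 genes called within set B, 49.5% had the same sign in the set A pair. Among the 3961 with an absolute log2 change of at least 1 in set B, 53.3% did.

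The first pattern is the weak response of the single set A pair in total RNA. A set A library that held only vehicle RNA is argued against, since the 12 genes at least 2-fold higher in all 6 light and heavy pairs, Car6 and Slc7a11 among them, had a median log2 ratio of 1.60 in the set A total RNA pair. A lower dose, as the headers name, stays open and cannot be told apart from the set, because dose and set divide the libraries alike. Slopes on the set B changes of total RNA over 2439 genes were 0.253 for set A, 0.140 for tag 2 and 0.726 for tag 4 in heavy polysomes. In light polysomes they were 0.238, 0.112 and 0.677. Set A lay above tag 2, by 0.113 in heavy polysomes, which a lower dose alone would not give if the tag 2 pools were sound. It lay well below tag 4, as a lower dose would give, so the slopes do not decide. A mixture of treated and untreated RNA, and a biological difference between cultures, were not tested.

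The second pattern is that total RNA and pools of one tag parted in the ATF4 list. A difference in scaling is argued against, since the tag 2 ratios in total RNA and heavy polysomes correlated across genes at only 0.340. The total RNA ratio lay outside the range of the 3 pools for 97.1% of the 35 list members in tag 2, 34 of them above, which restates the pattern, so different cultures for total RNA and pools of that tag cannot be told apart from other causes. In set A the share was 94.3%, with 30 below the pools, and in the third tag pair, where the tags differ between total RNA and pools, it was 82.9%. No biological explanation was tested.

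The third pattern is the tag 4 pair of ribosome-free libraries. The same 12 genes had a median log2 ratio of 0.0905 in this pair, and a library labelled halofuginone that holds vehicle RNA may account for it. That median largely restates the lack of response in this pair, so it cannot tell this explanation from other causes. The ratio does not tell which library of the pair departs from its label, so a vehicle library that holds halofuginone RNA stays open too. A swap of both libraries is argued against by that median and by a lower quartile of -0.022, since a swap needs values well below 0. For these 12 genes, that untranslated RNA carries no response is argued against by medians of at least 2.34 in the other ribosome-free pairs. This does not extend to a broad response. Over 2439 genes changed in set B of total RNA, 80.0% had the same sign in the ribosome-free set A pair, with a slope of 0.224. In the tag 2 pair 54.7% did, with a slope of 0.069, and in the tag 4 pair 47.4%, with a slope of -0.003. The genes were picked from light and heavy pools alone, and the least mean of 5 CPM in that choice replaced 1 CPM after the values were seen, with verdicts that were alike under both.

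For the comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. In total RNA, the ribosome-free pool and both differences of differences the real split called 0 genes and the highest other split 0, so all 10 of 10 gave as many. In light and heavy polysomes the real split called 0 and the highest other 111 and 99. That split puts vehicle set A, halofuginone set A and halofuginone tag 4 together and points to a structure of the samples, while among the 4 splits that part all 3 tag pairs the highest other called 0. In vehicle cells the real split of heavy against ribosome-free libraries called 3616 genes and the highest other 0, so 1 of 10 splits gave as many.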

How the results depend on the processing

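The fits within set B, with the set as a covariate and without the ribosome-free tag 4 library were chosen after the data were seen, and the other alternatives were planned. The spread between libraries limits the halofuginone comparisons, and the cause of the moves given here was not tested unless stated. In total RNA the count of 0 genes became 515 with DESeq2, 6 with the set as a covariate, 9337 within set B and 0 to 8246 with single libraries left out, the highest without the set A halofuginone library. In simulated counts DESeq2 made 40 calls among unchanged genes of total RNA, 33 in ribosome-free RNA, 37 in light and 23 in heavy polysomes, 13 in heavy relative to total RNA and 19 relative to ribosome-free RNA. Those simulations also held genes with known changes, so these are not counts expected without any change. Ribosome-free counts stayed at 0 except with the block. Light polysomes gave 39 with DESeq2 and 47 without a filter, and heavy polysomes 78, 105 without a filter and 1 with all 24 libraries in one model. Heavy relative to total RNA gave 1 with DESeq2, 1 without a filter and 0 to 1 with libraries left out. Heavy relative to ribosome-free RNA gave 7 without a filter and 1 within set B. In vehicle cells 3616 became 5503 with all 24 libraries, 784 to 5524 with a replicate left out and 5524 within set B. All 24 libraries in one model moved the median of all genes there by 0.146.

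With the replicate block the counts became 15 in the ribosome-free pool, 3 in light and 2 in heavy polysomes, and the list calls that changed in these paired pools stand beside their results; no other call of a list or count in a paired comparison moved past its threshold or by over 1.5 times. For total RNA the tags do not pair all libraries. Same-tag correlations were 0.385, 0.429 and 0.007, against highest values with another tag of 0.012, 0.481 and 0.481, so set A alone paired. Between total RNA and heavy polysomes set A and tag 2 paired in vehicle (0.177 against 0.103 and 0.339 against 0.124). The third pair did not (-0.022 against 0.124), nor did any with halofuginone (as low as -0.382). In both comparisons the block left counts of 0. In heavy relative to total RNA it moved the camera adjusted p of aminoacyl-tRNA synthetases to 0.0262 (0.847 with an estimated correlation), ribosomal proteins to 0.0734, p53 targets to 0.148 and nuclear-retained RNAs to 0.424.

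With other choices of libraries a pair of list medians reversed, besides the small medians that turned under another scaling. Oxidative phosphorylation in the ribosome-free pool turned to 0.14 within set B, and DNA replication in heavy relative to ribosome-free RNA to -0.16 without the tag 4 library labelled halofuginone. The estimated correlation ended all 88 camera calls over the 7 comparisons. With the GC and length correction, and its test on fold changes, the proline-rich set of vehicle cells passed its threshold at -0.46. Of named genes 170 kept direction and side of the threshold with DESeq2 and 21 newly passed, and with median-of-ratios factors 197 did so.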

Other observations

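All values in this part were chosen after the data had been seen. Some genes, most of them outside the fixed lists, stood in the same direction in each of the 6 light and heavy pairs. The 12 genes at least 2-fold higher in all of them included the secreted carbonic anhydrase Car6, the muscle-type cytochrome oxidase subunit Cox6a2, the skin adhesion protein Cdsn, the actin regulator Avil, the teneurin Tenm4, the ATP-gated channel P2rx3, Angptl6, Gdap1l1, and from the ATF4 list Slc7a11 and Aldh1l2. Their median log2 ratios in heavy polysomes were 3.69 in set A, 2.43 for tag 2 and 3.28 for tag 4. Cdsn stood at 5.29, 3.06 and 4.79 in the same pairs, and Car6 at 6.09, 5.66 and 6.23. In total RNA the medians were 1.60 in set A and 4.22 and 4.13 in set B.

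The 19 genes at least 2-fold lower in all 6 pairs included Dpt, Mgp, the protease gene Plat, the cysteine dioxygenase Cdo1, the thyroid hormone deiodinase Dio2, the acetyl-CoA synthetase Acss2, the cilia gene Cfap100, the receptor Trem2, Ly6c1 and Akr1c18. No shared function of these genes was tested. Their median log2 ratios were -1.69, -1.53 and -3.97 in heavy polysomes and -1.46, -1.39 and -3.76 in light polysomes. In total RNA they were -0.69 in set A and -3.90 and -3.85 in set B. Ratios of single pairs have no replicate error, and both sets were picked for their direction in these pools, so the values there are no test.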
